A study of Mus musculus with 12 samples.

How the data were processed

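Liver RNA from 6 wild-type and 6 A1cf -/- mice (KO) of the C57BL/6 strain was extracted with a miRNeasy kit, made into libraries with the TruSeq RNA kit from total RNA and sequenced on an Illumina HiSeq instrument, per the labels' protocols and the series' design text. Samples were grouped by the genotype given in their labels, and each library is named by its group and the number in its title. The groups share no library number.

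The deposited table held raw counts of fragments per gene name, made by the authors with featureCounts 1.5.0-p2 on the exons of the GENCODE M8 annotation, per the file headers. The command there counts fragments of read pairs over exons and sets no option for strand, for reads mapping to several places or for leaving out duplicates. Alignment files are named there as trimmed, duplicate-marked and merged. The submitters' processing notes name STAR, DESeq2 and the mm10 build, without versions or settings. Without a strand option, reads from overlapping genes on opposite strands cannot be assigned to 1 of them, and by that tool's default reads over several genes are not counted. Gene positions are those of the deposited table, on mm10. No row lacked a gene name and no name was repeated. The deposited table also gave an exonic length per gene, another value per gene, which was used only for the length check.

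Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10), library sizes were scaled by TMM, and KO was compared with WT by the robust quasi-likelihood test (glmQLFit, glmQLFTest) with genotype as the only term. P-values were adjusted by Benjamini and Hochberg over 13706 tested genes, and 0.05 was the threshold. A gene is said to have risen or fallen only past that threshold. The standard error of a log2 fold change is its size divided by the square root of F. CPM are scaled by TMM, and a prior count of 2 was used for log2 CPM. A count of 0 in a library allows up to 3 counts, or 0.059 to 0.131 CPM at these depths. Floors cover counting error only, while intervals were taken over genes as if these were independent and leave out the variation between mice.

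Gene lists (27) and cell type marker lists (12) were written before the data were examined, as was the comparison of KO with WT. Some later tests were chosen after results were seen, and the text says so where they appear. Lists were tested with camera (preset correlation 0.01), adjusted over the 39 lists together, and again with an estimated correlation and with fry. None of the 9 lists past the threshold held with an estimated correlation or in fry's test of a common direction, while 14 of 39 passed fry's test of change in either direction. Most other groupings of the libraries passed at least as many lists in camera with the preset correlation, as given below. Calls made with that setting are therefore weak evidence by themselves. Members were also adjusted over the list alone. Genes were named by a rule fixed beforehand. It took 8 genes of editing, lipoprotein assembly and fructose use whatever their result. It took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM and complete separation of the groups, passing over unnamed gene models (2 among the rises, 0 among the falls). From each list it took up to 4 members past the threshold with the smallest p, or, where none passed, at most 2 as values. Members of marker lists without a call are mostly given as counts, a choice made after their values were seen. Of the genes this rule took, 2 are not reported here.

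The steps were tested on simulated data with known answers. In 13706 genes simulated from the real means and library sizes for 6 against 6 libraries, 200 genes were changed. The test recovered 44% of those changed 1.5-fold, 86% of those changed 2-fold, 94% of those changed 4-fold and 96% of those changed 8-fold, and 5.59% of its calls were false. A list of planted small shifts was called by camera and 0 of 40 unchanged lists were. Simulated genes varied independently, without the structure that real libraries share, so the false share of 5.59% need not hold for the real calls. For the same reason these 40 lists do not show how often camera calls lists whose members vary together. Members of some real lists did so, with an estimated correlation of 0.848 for cholesterol synthesis. The matched comparison of 3′ UTR motifs recovered a planted difference of 15 percentage points as 15.6 on average over 20 runs, and called 1 of 20 unchanged sets. Untranslated regions were taken from the GENCODE annotation given with the mouse reference, in a later release of the same build, by gene symbol.

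The other settings, most of them fixed before the data were examined, were RLE size factors, library totals only, no low-count filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, the library number range as a covariate, only the libraries numbered 573 to 602, each library left out in turn, and a threshold of 0.01. Surrogate variables from sva 3.50.0 (3 were found) and a fit without the 2 deepest libraries were added after seeing the data. Chance was examined with 100 of the 462 splits of the 12 libraries into 2 groups of 6, the real one included. Editing, splicing and isoform use need reads or exon counts and were not analysed here.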

Results

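Liver RNA of wild-type (WT) mice and of mice lacking A1cf (KO) was compared, with 6 libraries of each genotype on the C57BL/6 strain. A1CF, the APOBEC1 complementation factor, is an RNA-binding protein of hepatocytes and enterocytes first known as a partner of the cytidine deaminase APOBEC1 in C-to-U editing of Apob mRNA. The series' design text describes the 6 libraries of each group as biological replicates. The deposited table held fragment counts for 46882 gene names, of which 26090 had at least 1 count and 13706 were abundant enough to be tested. Total counts per library lay between 22129092 (KO 584) and 51082317 (KO 588), and between 25898171 and 40597491 in WT. Spearman correlations between libraries ran from 0.934 to 0.942 over all 46882 gene names, those without any count included. No pair of libraries within a group was alike within counting noise (chi-square per degree of freedom 15.1 to 272). All 12 libraries carried Y-linked transcripts (Ddx3y at 561 to 1686 counts) and almost no Xist (0 to 6 counts), so both groups were male by these genes.

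The targeted transcript was examined first. A1cf (chromosome 19, 31868761 to 31949406, plus strand, mm10) fell from 50.9 ± 2.3 CPM (counts scaled to library size; mean ± SD, n = 6) in WT to 10.6 ± 1.5 CPM in KO (n = 6), a log2 fold change of −2.26 with a standard error of 0.09 (adjusted p = 1.1e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). An exact permutation test on log2 CPM gave a two-sided p of 0.002165, the smallest that 924 assignments of 6 against 6 libraries can give. Every KO library (8.20 to 12.6 CPM) lay below every WT library (47.9 to 53.8 CPM). The KO mean was 20.9% of the WT mean, so fragments assigned to the locus remained. Counts summed over the whole gene do not tell which exons those fragments came from.

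The comparison of KO with WT liver asked which transcripts differ when A1cf is missing. Among genes whose groups separated completely, the largest falls were in asparagine synthetase (Asns), which fell by 4.03 on the log2 scale, from 8.84 ± 6.60 to 0.564 ± 0.503 CPM, and in the oxysterol hydroxylase Cyp39a1, which fell by 2.53 (24.1 ± 13.04 to 4.23 ± 2.30 CPM), with adjusted p-values of 0.0080 and 0.0097. The largest rise was in Cyp2b9, a cytochrome P450 that is usually more abundant in female mouse liver, from 0.765 ± 0.376 to 52.8 ± 37.0 CPM (log2 fold change 6.12 ± 0.73, SE; adjusted p = 0.0015). Mogat2, a monoacylglycerol acyltransferase of triglyceride synthesis, rose from 0.271 ± 0.256 to 2.77 ± 1.60 CPM (log2 3.38 ± 0.58, SE; adjusted p = 0.0078). Values are means ± SD over 6 libraries unless SE is stated, and these 4 genes separated the genotypes completely.

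**Figure D1:**
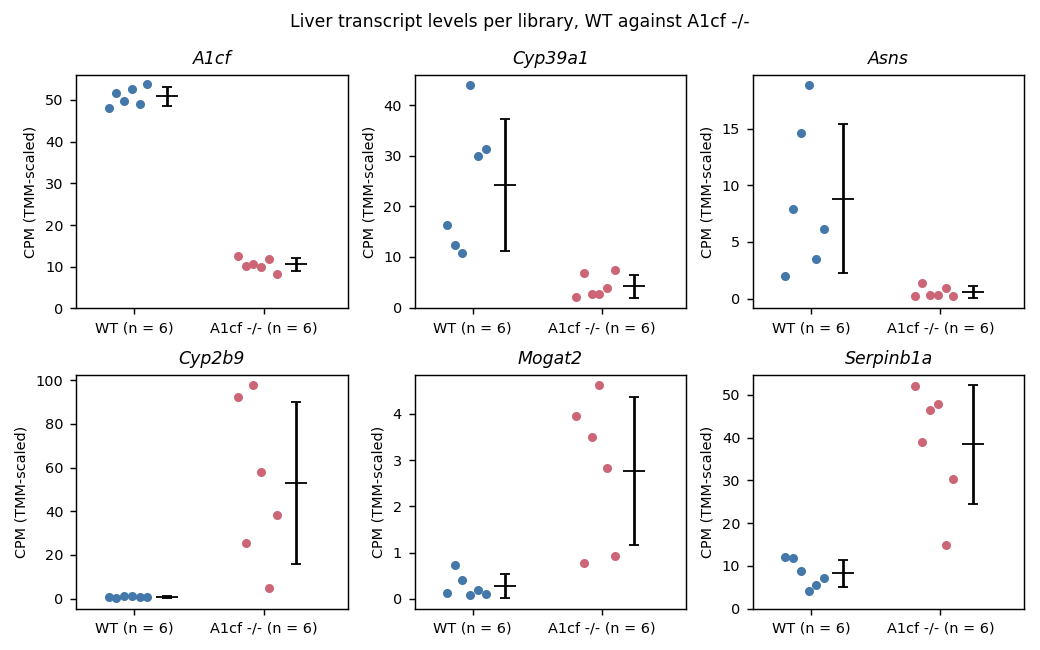
Points are the 6 WT and 6 A1cf -/- libraries, in CPM scaled by TMM on linear axes, for A1cf, Cyp39a1, Asns, Cyp2b9, Mogat2 and Serpinb1a; horizontal marks with bars are group means ± SD. No KO library overlaps the WT range for these genes, while Cyp2b9 spreads from 4.89 to 97.6 CPM among KO libraries.

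In all, 523 of the 13706 tested genes (3.82%) passed an adjusted p of 0.05, with 236 higher and 287 lower in KO. Of these, 120 changed at least 2-fold, 88 upward and 32 downward. In 318 of the 523 genes every library of one genotype lay above every library of the other. Over all tested genes, 452 (3.3%) were separated in this way, against 0.216% by chance for 6 against 6. With library totals as the only scaling, 266 genes rose and 139 fell, so the balance of directions depended on the scaling. The count was 57 in the 3 WT and 5 KO libraries numbered 573 to 602, and 206 when the 2 deepest libraries, WT 573 and KO 588, were left out.

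Genes that rose were less abundant than genes that fell. The median mean level was 2.08 log2 CPM for genes that rose and 4.68 for genes that fell, against 3.58 for the other tested genes, and median absolute log2 changes were 0.865 and 0.466. Among the 2844 genes with a mean below 1 log2 CPM, 71 rose and 19 fell, and the median log2 fold change of the bin was 0.19. Among the 1948 genes above 6 log2 CPM, 12 rose and 60 fell, with a median of −0.07.

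**Figure D2:**
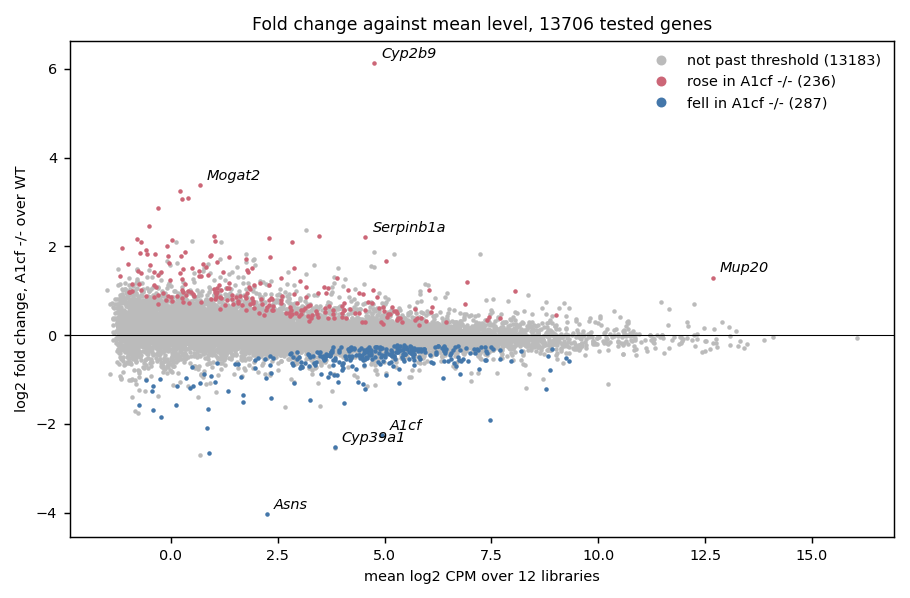
Each point is 1 of 13706 tested genes, with the mean log2 CPM over 12 libraries on the horizontal axis and the log2 fold change of KO over WT on the vertical axis. The 236 genes that rose (red) lie mostly at low levels and the 287 that fell (blue) at middle and high levels.

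Other large falls, with complete separation, were in Mtnr1a, a melatonin receptor (log2 −2.09), Mthfd1l, a mitochondrial folate enzyme (−1.67), Serinc2 (−1.52), Ccdc171 (−1.50), Zap70, a kinase best known from T cells (−1.47), and Bhlhb9 (−1.34). Their adjusted p-values in edgeR's quasi-likelihood test lay between 8.6e-04 for Zap70 and 0.019 for Bhlhb9. Serinc2 and Zap70 had WT means of 24.6 and 13.9 CPM, whereas Mtnr1a and Mthfd1l stood at 2.77 and 2.68 CPM. The other large rises were in Hspa1a (3.24), Lrtm2 (3.10), the protease inhibitor gene Serpinb1a (2.21), Ly6d (2.10), the homeobox gene Prrx1 (1.88), the phosphodiesterase genes Pde6c (1.80) and Pde1a (1.71), and Rasl10b (1.77). Serpinb1a went from 8.29 ± 3.21 to 38.4 ± 13.9 CPM (adjusted p = 0.0043) and Pde1a from 1.55 ± 0.32 to 5.06 ± 0.94 CPM (adjusted p = 1.5e-04, n = 6 per group, edgeR's quasi-likelihood test). Hspa1a, an inducible chaperone gene with a near-identical neighbour that may share its reads, was at 7.37 CPM in KO 591 and at 0.556 to 1.56 CPM in the other KO libraries. Without KO 591 its log2 change was 2.16. The log2 change of Mogat2 was 3.99 without WT 590, and that of Cyp39a1 was −1.89 in the libraries numbered 573 to 602. WT levels of Cyp39a1 were 10.8 to 16.4 CPM in that range and 29.9 to 43.9 CPM in WT 776 to 778. The ranges hold unequal shares of KO libraries. Within them, differences in mean log2 CPM were −1.96 and −2.22 for Cyp39a1 and −0.92 and −1.09 for Bhlhb9, smaller than over all libraries. The second range has 1 KO library. Lrtm2 lies within another annotated gene, Cacna2d4, and no strand option was given in the counting command.

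Genes of the editing machinery and of lipoprotein assembly were named in advance. Apobec1 was at 10.6 ± 1.2 CPM in WT and 11.2 ± 2.2 CPM in KO (log2 0.09 ± 0.12, SE; adjusted p = 0.72). Rbm47, which encodes another APOBEC1 cofactor, rose by 0.31 (adjusted p = 0.039, edgeR's quasi-likelihood test), and was the only one of 12 tested editing partners past the threshold, also over the list alone. It fell short in 9 of the 12 fits with 1 library left out. The log2 changes of Apob (−0.09 ± 0.10, SE), Mttp (−0.11 ± 0.14), Tm6sf2 (−0.18 ± 0.12) and Khk (−0.32 ± 0.20) did not pass. Of 21 tested transcripts with reported APOBEC1 editing sites, Rnf128 (−0.30) and Atp6ap2 (−0.44) fell; adjusted over the list alone, 2 fell and 1, Clic5 (0.53), rose. Editing itself was not analysed here.

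None of 37 genes of VLDL assembly and plasma lipoprotein handling passed over all genes. Adjusted over the list alone, 2 passed upward (Vmp1, 0.47, and Apoc2, 0.46) and 2 downward (Cideb, −0.30, and Mia3, −0.24); Apoc2, Mia3 and Clic5 were named after their values were seen. Of 29 genes of fatty acid synthesis and triglyceride storage, Me1 (−0.62), the malic enzyme that supplies NADPH, and Agpat2 (−0.28), an acyltransferase of phosphatidic acid synthesis, fell, as they did when adjusted over the list alone. None of 31 genes of fatty acid oxidation and ketogenesis and none of 23 genes of bile acid synthesis and transport passed, over all genes or over the list alone; their smallest p-values belonged to Acadvl (−0.23) and Bdh1 (−0.45), and to Cyp7b1 (−0.85) and Slco1a4 (0.79). Cyp39a1 and Mogat2 were in none of these lists. Of 26 genes of fructose, glycerol and glycolysis, the fructose transporter gene Slc2a5 rose (0.66), and Gckr (−0.32), which encodes the glucokinase regulator, and glycerol kinase Gk (−0.58) fell, with the same count over the list alone. None of 24 genes of gluconeogenesis and glycogen passed either way (Gpt2 0.44, Pygl −0.31).

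The cholesterol synthesis list stood lower in KO, with 24 of 25 members below 0 and a median log2 change of −0.33 (camera with a preset correlation of 0.01, adjusted p = 0.0031). Only Hsd17b7 (−0.77) passed singly, also over the list alone, and the list's adjusted p was 0.87 with an estimated correlation. Without WT 590 the list's median was −0.06 and its call was lost, as it was without KO 584 (−0.23) or KO 780 (−0.22). Of 30 genes of the unfolded protein response, 5 fell and 1 rose, with the same numbers adjusted over the list alone, and the list's median was −0.27 (camera adjusted p = 3.2e-05; adjusted p = 0.75 with an estimated correlation). The members that fell were Asns, the chaperone genes Hyou1 (−0.59), Hspa5 (−0.51, encoding BiP) and Dnajc3 (−0.41), and Syvn1 (−0.46), an ER ubiquitin ligase gene; Atf3 (1.77), a stress-induced transcription factor gene, rose. Asns belongs to the amino acid response as much as to ER stress. Dnajc3 and Syvn1 are named here after their values were seen, and both fell short in most fits with 1 library left out. Respiratory chain genes had a median of −0.12 (camera adjusted p = 0.0031; adjusted p = 0.87 with an estimated correlation), no member passing over all genes and 3 falling when adjusted over the list alone (Sdhd −0.42, Uqcrc2 −0.37 and, named after its value was seen, Atp5c1 −0.29). This list was past the threshold in neither the libraries numbered 573 to 602 nor the fit without KO 602. Cytosolic ribosomal protein genes had a median of −0.11 with 29 of 30 members below 0 (camera adjusted p = 0.0031; adjusted p = 0.87 with an estimated correlation) and no single call, over all genes or over the list alone (Rps6 −0.23, Rpl14 −0.22).

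The interferon response list stood higher in KO, with 27 of 29 members above 0 and a median of 0.77 (camera adjusted p = 5.3e-07; adjusted p = 0.75 with an estimated correlation). Oas1a (1.42) and Oas2 (1.17), both antiviral oligoadenylate synthetase genes of a family with close copies, and the guanylate-binding protein gene Gbp3 (1.21) rose; adjusted over the list alone, 4 rose, the other being Ifi44 (1.12), named after its value was seen. Fibrosis and extracellular matrix genes had a median of 0.34, all 19 tested members lying above 0 (camera adjusted p = 0.0031; adjusted p = 0.87 with an estimated correlation), and none passed singly, over all genes or over the list alone (Col4a2 0.75, Col4a1 0.58).

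Markers of non-parenchymal liver cells were higher in most KO libraries. The mean log2 CPM of the pooled Kupffer, endothelial and stellate markers was 3.37 to 4.08 in WT and 4.12 to 4.45 in KO apart from KO 584, which lay within the WT range at 3.77 and had less Clec4f (26.5 CPM) and Csf1r (14.8 CPM) than any WT library. All 11 Kupffer cell and macrophage markers lay above 0, with a median log2 change of 0.67 (camera adjusted p = 2.1e-04; adjusted p = 0.78 with an estimated correlation). None passed over all genes and 10 rose when adjusted over the list alone; Csf1r was at 0.70 and Clec4f at 0.75. Among 11 stellate cell and fibroblast markers, Pdgfrb (0.43) and Lrat (0.68) rose and the median was 0.50 (camera adjusted p = 1.5e-04; adjusted p = 0.75 with an estimated correlation), with 4 rising over the list alone, Colec11 (0.50) and Reln (0.48) among them and named after their values were seen. Of 10 sinusoidal endothelial markers, Stab2 (0.48) rose, also over the list alone, and the median was 0.20 (camera adjusted p = 0.028; adjusted p = 0.87 with an estimated correlation). This last list lost its call without WT 590, WT 601, WT 777 or KO 780. The 7 tested hepatocyte markers all lay below 0, with a median of −0.22 (camera adjusted p = 0.17) and no single call, over all genes or over the list alone (Hnf4a −0.22, Apoa1 −0.29).

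**Figure D3:**
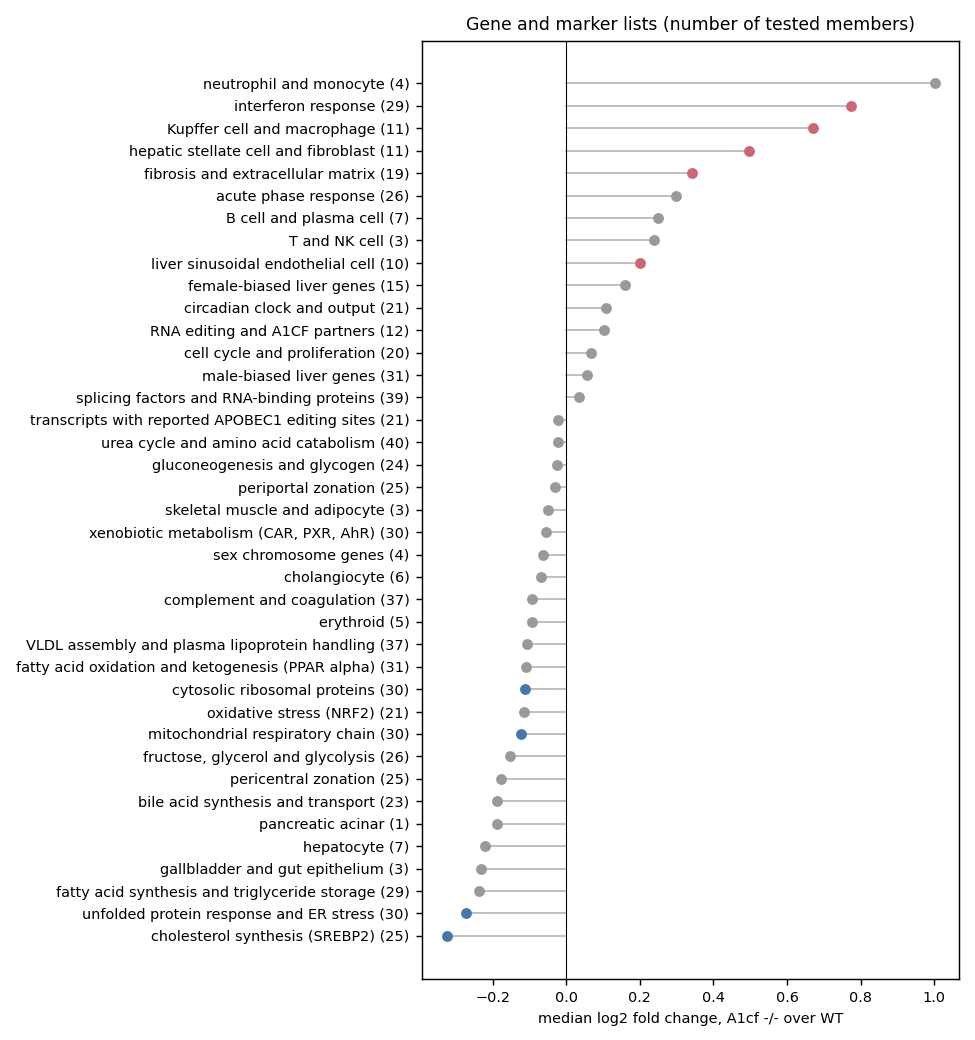
Each point is the median log2 fold change of KO over WT of 1 of 39 gene and marker lists, with the number of tested members in parentheses; red (higher) and blue (lower) mark the 9 lists past an adjusted p of 0.05 in camera with a preset correlation of 0.01, and grey the other 30. Medians ran from −0.33 for cholesterol synthesis to 1.00 for the 4 neutrophil and monocyte markers, which did not pass. At least 9 lists passed in 78 of 100 splits of the libraries, so colour alone does not mark a difference between the genotypes.

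Among drug-metabolising genes, Cyp2b9 and the sulfotransferase gene Sult1a1 (0.46) were the 2 of 30 that rose, also over the list alone. Of 15 tested female-biased genes, Cyp2b9 was the only one to pass, and of 31 male-biased genes, the major urinary protein genes Mup20 (1.29) and Mup21 (1.00) rose, both also over the list alone. Mup20 went from 3810 ± 879 to 9323 ± 1318 CPM (n = 6 per group; adjusted p = 0.0013 in edgeR's quasi-likelihood test). Mup and Cyp2b genes have near-identical copies between which reads can be divided, so single-gene values are uncertain. Of 21 oxidative stress genes, Gclc (−0.76), the catalytic subunit gene of glutathione synthesis, and Sod2 (−0.32) fell and Cbr3 (1.08) rose, and over the list alone G6pdx (0.56), named after its value was seen, rose as well.

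In the remaining lists few or no members passed. Of 25 periportal genes, Cdh1 (−0.76) fell, also over the list alone. None of 25 pericentral genes passed over all genes and 2 fell over the list alone, Gulo (−0.57) and Notum (−0.46). Of 37 complement and coagulation genes, F11 (−0.35) fell over all genes and none over the list alone. No gene passed, over all genes or over the list alone, among 26 acute phase genes (Lbp −0.30, Steap4 0.56), 21 clock genes (Noct 0.85, Ciart −0.78), 40 genes of the urea cycle and amino acid catabolism (Acmsd 1.55, Bhmt 0.69), 39 splicing and RNA-binding factors (Clk4 0.27, Ptbp2 −0.54), 20 cell cycle genes (Mki67 1.51, Foxm1 0.93) and 4 tested sex chromosome genes. The tested markers of cholangiocytes (6), B and plasma cells (7), red cells (5), pancreatic acini (1), gallbladder and gut (3) and muscle and fat (3) held no call over all genes or over the list alone. Of 3 T and NK cell markers, Ptprc (0.64), and of 4 neutrophil and monocyte markers, Csf3r (0.96), passed over the list alone and not over all genes; both were named after their values were seen. None of these lists passed camera. In 7 lists that did not pass, the median and the mean differed in sign: drug metabolism (median −0.05, mean 0.26), muscle and fat markers (−0.05 and 0.72), B and plasma cell markers (0.25 and −0.06), and, all with a negative median and a mean of at most 0.05, transcripts with editing sites, amino acid catabolism, oxidative stress and cholangiocyte markers. Camera's direction followed the median except for drug metabolism and muscle and fat.

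The labels number the libraries 573 to 602 and 776 to 780, a split that holds 3 WT and 5 KO against 3 WT and 1 KO libraries, and no test was made within the second range, which has a single KO library. Of 54 genes called in the first range and tested in the fit of all libraries, 54 had the same direction in the second, where the more common direction over all genes took 52.1%. This agreement rests on KO 780 alone and says nothing of the spread between KO mice there. With the number range as a covariate, 684 genes passed, 429 of them shared with the 523. Of 45 named genes with a call, 22 kept it in all 12 fits with 1 library left out: A1cf, Asns, Bhlhb9, Ccdc171, Cyp2b9, Cyp39a1, Gclc, Hyou1, Lrtm2, Mogat2, Mthfd1l, Mtnr1a, Mup20, Mup21, Oas1a, Oas2, Pde1a, Pde6c, Prrx1, Serinc2, Serpinb1a and Zap70. The other 23 fell short in at least 1 such fit, and most of them in most fits, so their rise or fall given above is less certain. Gckr and Sod2 fell short in 11 of the 12, Agpat2, Cdh1, F11 and Me1 in 10, and Atf3, Cbr3, Gbp3, Gk, Ly6d, Rbm47, Rnf128, Slc2a5, Stab2 and Sult1a1 in 9. Atp6ap2 fell short in 6, Hspa5 and Lrat in 5, Hsd17b7 and Hspa1a in 4, Pdgfrb in 3 and Rasl10b in 2.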

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

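The tests of hepatocyte share, of alleles linked to the A1cf locus and of other A and T rich motifs were chosen only after the result was seen. Of 218 groups of 6 values examined (totals, mitochondrial shares and the genes named in the text, in WT and KO), 15 held a library far from the other 5 by Dixon's ratio of gap to range above the 95% critical value; chance flags about 1 in 20.

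Total counts stood apart in WT 573 (40597491 against 25898171 to 28982499, ratio 0.79) and KO 588 (51082317 against 22129092 to 27338946, ratio 0.82). In KO 602, Serinc2 was at 14.6 CPM (others 5.95 to 9.12, ratio 0.632), Steap4 at 245 CPM (others 58.0 to 125, ratio 0.644), Me1 at 57.8 CPM (others 79.3 to 85.7, ratio 0.771), Rasl10b at 5.24 CPM (others 1.88 to 3.04, ratio 0.655), Dnajc3 at 188 CPM (others 128 to 146, ratio 0.692) and Atp5c1 at 169 CPM (others 221 to 233, ratio 0.823). Acmsd was at 88.8 CPM in KO 780 (others 23.5 to 38.7, ratio 0.767) and Hspa1a at 7.37 CPM in KO 591 (others 0.556 to 1.56, ratio 0.853). In WT, Hspa5 was at 528 CPM in WT 777 (others 722 to 778, ratio 0.778), Ccdc171 at 7.59 CPM in WT 601 (others 3.81 to 4.58, ratio 0.797), Dnajc3 at 231 CPM in WT 590 (others 181 to 194, ratio 0.742), Reln at 42.4 CPM in WT 778 (others 22.4 to 29.7, ratio 0.633) and Hist1h4h at 1.27 CPM in WT 601 (others 0.559 to 0.715, ratio 0.78).

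The number of genes changed was larger than in any other split drawn. Of 100 splits, 1, the real one, gave as many as 523, and the highest of the others gave 421. This is the lowest share that 100 splits can show, and splits that were not drawn could give as many. The split with 421 genes set WT 573, 776 and 778 with KO 574, 584 and 780 against the rest. The next highest gave 4 and the median of the 99 others was 0, so the 421 genes point to another structure among the samples; the rest were WT 777 and the 5 libraries with high acute phase transcripts. The number of gene and marker lists past the threshold is different. At least 9 lists passed in 78 of 100 splits. The 99 others gave a median of 12 lists and at most 21, so chance cannot be excluded for that number. Groupings that mix the genotypes thus passed lists as readily as the real one. A list's p-value from camera with the preset correlation therefore does not by itself set KO apart from WT.

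The first pattern is the higher level of Kupffer, endothelial and stellate markers in KO. The pooled 32 markers had a median log2 change of 0.488 (bootstrap 95% interval 0.378 to 0.565), all 32 lying above 0. Of 100 splits, 1, the real one, gave as large a median, the highest of the others being 0.466. The pooled lists are the marker lists that passed camera in this comparison, and every split was scored on that same pool. The splits therefore do not measure how often chance yields some pool of lists as high. A lower share of hepatocyte RNA in KO would raise the markers of every other cell type alike, but these types moved apart. The 4 neutrophil and monocyte markers were all higher, with a median of 1.00 (0.182 to 1.20), while the 21 cholangiocyte, lymphocyte and erythroid markers had a median of −0.00113 (−0.136 to 0.238). Together these 25 had a median of 0.109 (−0.122 to 0.290), below the interval of the pooled markers, as had the 32 markers of all other types on the lists (0.00554, −0.136 to 0.236). The pooled lists also differed among themselves, with medians of 0.67 (Kupffer), 0.50 (stellate) and 0.20 (endothelial). The last lay inside the interval of the 25 other markers. The intervals leave out that members vary together (estimated correlation 0.761 for Kupffer markers). Some of the 25 were scarce, as Cd3e (0.291 CPM in WT) and Cd79a (0.526 CPM in WT). An equal rise of all other types was not seen. For these reasons the comparison cannot decide how far a lower hepatocyte share accounts for the pattern. One aberrant library does not account for the pattern, since the lowest median in the 12 fits without 1 library was 0.410, without WT 777. More such cells, more RNA in each of them, or a difference in the piece of liver taken stay open and were not tested.

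The second pattern is the rise of scarce genes and fall of abundant ones. The medians of genes below 1 and above 6 log2 CPM lay 0.263 apart, as large as in 1 of 100 splits (highest of the others 0.253). The pattern itself was taken from these data, so the splits do not measure how often chance yields some such pattern. Unequal depth is argued against, since the gap was 0.272 after every library was thinned to 22129092 counts (0.241 to 0.319 without 1 library). With the mean level of the pooled markers as a covariate the gap was 0.188, and 0.0633 to 0.243 without 1 library, so RNA from non-parenchymal cells may contribute and cannot be told apart from genotype here, because the marker level itself differs between the groups. In that fit 54 genes passed, with a median standard error 1.43 times that of the fit with genotype alone.

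The third pattern is the set of genes that fell. Alleles carried along with the A1cf locus and acting on genes near it are argued against as the cause of most falls. Of the 286 genes that fell besides A1cf, 1.40% (4 genes, exact 95% interval 0.382 to 3.54) lay on chromosome 19 within 20 Mb of it. That window held 233 tested genes besides A1cf, of which 4, Pde6c among them, rose. The odds ratio of a call inside against outside it was 0.896. Effects of linked alleles on single genes in the window, or on genes elsewhere, were not tested. Exonic length is argued against as the whole cause, since 95.1% of the genes that fell (272 of 286) were still called lower after a loess correction on length. That correction was small, with a median absolute offset of 0.0207 on the log2 scale, against a median absolute change of 0.466 for genes that fell. It thus had little room to remove calls, and whether these genes differ in length from unchanged genes was not tested. A1CF is known to bind U and A rich sequence, and a motif test written beforehand came out positive: the motif UAAUU followed by A or G occurred in the 3′ UTR of 59.2% of 267 genes that fell and 47.2% of 3 matched unchanged genes each, a difference of 11.99 percentage points (bootstrap 95% interval 6.49 to 17.6; one-sided permutation p = 4e-05), against −2.36 points (p = 0.8) for genes that rose. Genes were matched on 3′ UTR length, GC and mean level, not on the cell type they come from. The permutation shuffled genes, not mice, and library splits were not used for this difference. Across the 9 other orders of the same 5 letters the highest difference was 7.241 points, inside the bootstrap interval, so A and T rich sequence in general stays open. Direct stabilisation of some of the transcripts that fell by A1CF is a hypothesis that may be followed up with binding data.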

How the results depend on the processing

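The surrogate variable fit and the fit without the 2 deepest libraries were chosen after seeing the data. A1cf kept its direction and call under all alternatives run (log2 −2.31 to −2.16). No named gene with a call changed direction; of 45 such genes, 22 were past the threshold in all 12 fits without 1 library, and 9 to 21 fell short in any one of them. In the libraries numbered 573 to 602, 38 of 45 fell short, with fewer samples in the fit. Of the 45, 24 fell short without the 2 deepest libraries, 27 at a threshold of 0.01, 14 without a low-count filter, 10 with library totals only, 9 with the number range as a covariate, 5 with limma-voom and 1 with surrogate variables; with a mean of at least 1 CPM it was 2 of 44, and with RLE factors or DESeq2 it was 0.

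For the 523 genes changed, KO against WT (236 genes that rose in KO, given as up, and 287 genes that fell in KO, given as down), DESeq2 called 1175 (548 up, 627 down), 521 of them shared with the 523; the libraries numbered 573 to 602 gave 57 (25 up, 32 down; 45 shared), a threshold of 0.01 gave 140 (57 up, 83 down), surrogate variables 1875 (863 up, 1012 down; 522 shared), and leaving out WT 573 and KO 588 gave 206 (95 up, 111 down; 187 shared). Library totals alone gave 139 genes down, with a median log2 shift of 0.047 over all genes. Without 1 library, counts ran from 266 to 638 genes, from 116 to 313 up and from 150 to 325 down; they were 1.5 times lower or more without WT 573 (312), 777 (266) or 778 (294) or KO 574 (315), 588 (319) or 591 (324). Beyond the fewer libraries, the cause was not tested. RLE factors, limma-voom, both filters and the number range moved the count by less than 1.5 times.

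Of 9 lists past the threshold, 0 passed with an estimated correlation and 0 in fry. Log2 values near 0 that had not passed changed sign: Mttp to 0.03268 with the number range as a covariate and 0.03961 in the libraries numbered 573 to 602, and Apobec1 to −0.008493 without KO 602 (up to 0.1408 without another library); the cause was not tested. The median of the acute phase list was −0.34 without KO 602, against 0.30. No paired analysis was possible because the groups share no library numbers. The sex covariate was not run, since all libraries were male by their Y-linked genes. At these depths 44% of 1.5-fold changes were recovered in simulation, so small changes can be missed.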

Other observations

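All tests in this part were chosen after the result was seen. Several genes outside the naming rule had very small p-values in edgeR's quasi-likelihood test and were picked after their values were seen. Gbas, a mitochondrial protein gene, rose by 1.66 on the log2 scale (15.6 to 49.4 CPM, adjusted p = 1.3e-06). Ttpa, which encodes the vitamin E transfer protein of liver, fell from 617 to 265 CPM (log2 −1.22, adjusted p = 1.2e-04). Pex5 (−0.87) and Pex7 (−0.68), the receptors that bring proteins into peroxisomes, both fell. Srpr (−0.56), the receptor of the signal recognition particle, fell from 199 ± 8 to 134 ± 5 CPM (SD, n = 6; adjusted p = 3.6e-04, edgeR). Phkb rose (0.74) and Itfg1 fell (−0.56).

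Srpr was 1 of 11 genes of ER targeting and ER-to-Golgi transport that fell, with 0 rising, among 104 tested genes taken by symbol family. Uso1 (−0.37), Srp9 (−0.42), Sec62 (−0.30), Emc7 (−0.48) and Lman1 (−0.26) were among them; Uso1, Sec62 and Lman1 fell short in some fits with 1 library left out. The family's median log2 change was small, −0.0685, with 72 members lower and 32 higher (camera p = 0.0095 with an estimated correlation of 0.0185). A median as large arose in 2 of 100 splits, the real one included, and the highest of the others was 0.0823. The family was picked because members had fallen, so neither camera nor the splits measure how often chance yields such a family. A small general fall of the early secretory pathway in KO is a hypothesis that these values allow. It cannot be told apart here from the fall of abundant genes, since no comparison matched on level was made. All tested genes above 6 log2 CPM had a median of −0.0698, and those from 4 to 6 log2 CPM had −0.027. The family's fall also depends on scaling, since with library totals alone the median was −0.019 and 3 genes fell.

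Histone genes were taken by symbol, as those that begin with Hist and a cluster number. All 8 tested genes of this kind were higher in KO and 5 rose, among them Hist1h4h (2.11), Hist1h2be (2.01) and Hist1h1c (1.02). Histone genes with other symbols were not part of this family. Hist1h1c went from 43.6 ± 6.0 to 88.2 ± 42.1 CPM (SD, n = 6), a call lost in most fits with 1 library left out. Hist1h4h (0.742 to 3.17 CPM) and Hist1h2be (0.343 to 1.42 CPM) were scarce. The median log2 change of all 8 was 1.10, as large in 1 of 100 splits (highest of the others 0.8744), and 1.09 and 1.15 under the other scalings. The family was picked because members had risen, so the splits do not measure how often chance yields such a family. The 20 cell cycle genes held no call, with 15 higher and 5 lower in KO, which does not exclude a difference in proliferation. Many histone transcripts lack a poly(A) tail, so a difference in RNA selection or quality between the groups may give the same values and was not tested. Histone copies also share sequence.

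Acute phase transcripts varied widely within both genotypes. Saa1 was at 8340 and 6920 CPM in WT 590 and WT 601 and at 3650, 1840 and 17500 CPM in KO 588, KO 591 and KO 602, but at 20.8 to 83.8 CPM in the other 7 libraries. The same 5 libraries had the highest Lcn2 (52 to 1730 CPM) and lay on 1 side of the first principal component. All 5 carry numbers between 573 and 602.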
